A study of Xenopus laevis with 15 samples.

How the data were processed

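The measurements are read counts per gene from 15 libraries of pooled whole Xenopus laevis embryos, 5 per group, each from 3 individuals. Per the labels' protocols, poly(A) RNA was selected from 250 ng of total RNA and libraries were made with a directional kit, which keeps the strand. Per the submitters' processing notes, the tools were Trim Galore, HISAT2, kallisto and edgeR, without versions. The genome build, the annotation, the read counter and its strand setting are not given in the sources used here. Whether reads of .L and .S homeologs, of other near-identical copies or of overlapping antisense genes were shared or dropped is therefore unknown, and values of such copies are uncertain.

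The authors deposited a table of raw counts for 37018 Entrez genes, of which 3220 had no count in any library. The authors also deposited 2 tables of their own comparisons, each with 28950 genes, holding log2 fold changes, log2 mean CPM, likelihood-ratio statistics (a score) and p-values with adjusted p-values; their filter and design are not given in the sources used here. Per the authors' deposited table, 764 genes passed an adjusted p of 0.05 at lead 630 (594 higher, 170 lower), of which 561 passed in the test used here too, all with the same sign. For lead 210 the authors' deposited table held 690 (577 higher, 113 lower), of which 480 passed here, all with the same sign.

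Gene symbols came from the RefSeq gene table of assembly Xenopus_laevis_v10.1, which matched 33597 identifiers; 1468 more were named from the authors' deposited tables and 1953 stayed unnamed. The 2 sources gave different symbols for 12815 identifiers, so some genes carry another name, or the other homeolog letter, in the authors' tables. A gene counted as a list member under either symbol without its .L or .S. No coordinates are given, because the build of the counts is unknown.

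Counts were tested with edgeR 4.0.16 in R 4.3.3: filtering by group with filterByExpr, TMM normalization (factors 0.977 to 1.03), 1 quasi-likelihood fit with robust dispersion over all 15 libraries with the group as the only term, and a contrast for each pair of groups. The biological coefficient of variation was 0.142. p-values were adjusted by Benjamini-Hochberg over the 27060 genes tested and called under 0.05. CPM values use TMM-scaled library sizes and are given as mean ± SD (n = 5), and log2 fold changes as estimate ± SE. Log2 CPM for principal components used a prior count of 2.

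The design, the alternatives, the rule for naming genes and 37 gene lists of pathways, stress responses and cell types were fixed before the data were examined. Lists had 13 to 133 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01), then with an estimated correlation and with fry, each adjusted over the 37 lists. For each comparison with control the named genes were those past the threshold with at least 1 CPM and a symbol that is no placeholder: the 6 largest changes each way and up to 2 members of each list by p. Some genes that the rule names are not reported here. Where fewer than 6 passed, the next by p were taken. The genes alad, mt4, hmox1, slc30a1, alas2, thrb, klf9 and dio3 were named whatever their p. For lead 630 against lead 210 the rule took 5 each way, or up to 3 each way by p where fewer passed. Other list members are named only where a small count called for it, chosen after their values were seen.

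Counts were simulated from the real means, dispersions and library sizes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery under that level was not measured. The test recovered 92.5% of 2-fold changes for lead 630 against control, 85.1% for lead 210 against control and 83.6% for lead 630 against lead 210, among 26909, 26938 and 26913 simulated genes. For 1.5-fold changes the shares were 68.7%, 44.8% and 55.2%, and 3.33%, 1.30% and 5.36% of the calls were false. Libraries of a group were checked for duplicates: over the 30 pairs, the chi-square per gene was 4.24 to 16.9, so all differed by more than sampling noise. The lowest value of any pair lay across groups, 3.815 between lead 210 A and lead 630 A, which carry the same replicate letter. The floor covers counting error only. SEs were back-calculated as the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. Intervals rest on these SEs, and both include the spread between pools. Such SEs are unreliable for fold changes near 0. For anpep.S the SE was 1.308 at a log2 fold change of 0 for lead 630 against lead 210. Against control its SEs were 0.329 at lead 630 and 0.337 at lead 210.

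Alternatives were other filters, other normalizations, DESeq2 1.42.0, limma-voom, edgeR's exact test, a fit on 2 groups alone, the replicate letter as a block, summed homeologs and leaving out each library. Shared controls were examined with 12 simulations, 20 splits of the controls and 12 simulations with split controls, and each comparison with 100 regroupings of its 10 libraries.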

Results

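RNA of whole embryos of the African clawed frog, Xenopus laevis, was sequenced after exposure to lead(II) nitrate. The frog's genome holds 2 related copies, called homeologs and marked .L and .S, of many genes, and each copy was counted as a gene of its own. Exposure began at about Nieuwkoop and Faber stage 29, 48 h after fertilization, and lasted 96 h at 21 °C, so that embryos were 6 days old at sampling. There were 3 groups of 5 libraries, each library made from a pool of 3 individuals: water alone (control) and 2 lead levels. The sample labels give these levels as 210 and 630 ng/L, and the treatment protocol gives the same figures in µg/L. The groups are therefore called lead 210 and lead 630, without a unit. Nothing in the labels says whether the pools of a group came from separate dishes or clutches, so p-values measure the spread between these pools.

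Total counts were 17.3 ± 4.57 M per library in controls (M, counts in units of 1e+06; SD, n = 5), 15.6 ± 3.81 M at lead 210 and 18.1 ± 5.91 M at lead 630, and single libraries ranged from 10.8 to 24.7 M. A count of 3, taken as the floor, stood at 0.277 CPM (counts per 1e+06 counts) in the shallowest library and 0.122 CPM in the deepest. On the log2 CPM scale the first principal component held 20.3% of the variance and the second 17.2%. After filtering on low counts, 27060 genes were tested in each comparison.

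The comparison of lead 630 with control asked which genes differ in embryos at the higher lead level. Genes of glutathione synthesis and of the NRF2 response, the transcriptional answer to oxidants and electrophiles, rose together: 31 of 58 measured members were higher and 0 were lower (33 and 0 when adjusted over the list alone), and the list's median log2 fold change was 0.65. The glutathione S-transferase gstp1.L (Entrez 398321) went from 27.4 ± 21.0 CPM in controls to 506 ± 126 CPM (SD, n = 5 each), a log2 fold change of 4.18 ± 0.41 (SE; adjusted p = 4e-05). The gene for the catalytic subunit of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis, gclc.S (Entrez 100137615), rose by 1.88 ± 0.10 on the log2 scale, from 15.7 ± 1.87 to 57.9 ± 4.94 CPM (adjusted p = 1.45e-09). The gene of malic enzyme, which supplies NADPH, me1.L, rose by 1.19 ± 0.07 (adjusted p = 1.85e-09), and the heme oxygenase genes hmox1.L and hmox1.S rose by 0.86 ± 0.11 and 0.93 ± 0.12. For each of these 5 genes all 5 exposed libraries lay above all 5 controls.

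The largest rises among named genes with a mean of at least 1 CPM were those of nmral1.L and nmral1.S, which encode NmrA-like proteins of the kind that bind NADPH. The .L copy (Entrez 108706289) rose 52.1-fold (SE 0.36 on the log2 scale) from a control level near the floor, 0.34 ± 0.251 CPM, to 19.0 ± 3.53 CPM (adjusted p = 4.97e-08). The .S copy rose by 4.49 ± 0.38, from 46.8 ± 23.8 to 1045 ± 347 CPM. They were followed by gstp1.L, by the sodium-phosphate cotransporter gene slc34a2.S (4.09 ± 0.65), by the aldo-keto reductase gene akr1c2.L (3.75 ± 0.34) and by the alcohol dehydrogenase gene adh1-a (3.50 ± 0.74, adjusted p = 0.0177). Controls of slc34a2.S and adh1-a stood at 0.234 ± 0.207 and 0.272 ± 0.0655 CPM, at the floor, so the size of their folds is uncertain, and the call of adh1-a ended without control A or control C (adjusted p up to 0.0706).

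Metal handling genes also moved, 9 of 38 upward and 2 downward (13 and 3 adjusted over the list alone). Metallothionein mt4.L (Entrez 394349), a small metal-binding protein, rose from 95.4 ± 12.0 to 735 ± 119 CPM, by 2.95 ± 0.16 on the log2 scale (adjusted p = 2.27e-09). The ferritin heavy chain gene fth1.2.L, whose product stores iron, rose by 2.45 ± 0.14, from 279.9 ± 36.0 to 1534 ± 251 CPM. The zinc exporter genes slc30a1.L and slc30a1.S rose by 0.43 ± 0.06 and 0.51 ± 0.09. The members that fell were the zinc importer gene slc39a4.S (-1.17 ± 0.22) and the manganese exporter gene slc30a10.S (-0.46 ± 0.11). In heme synthesis and its transporters 4 of 23 members rose and 0 fell (8 and 0 adjusted over the list alone), namely the transporter genes abcb6.L (0.72 ± 0.06, adjusted p = 3.28e-07) and abcb10.S (0.99 ± 0.11, adjusted p = 9.64e-06; a pseudogene per the authors' gene name), alas1.S and tmem14c.L. The gene of aminolevulinate dehydratase, the heme enzyme that lead is known to inhibit, did not pass: alad.L differed by 0.24 ± 0.10 (adjusted p = 0.317) and alad.S by 0.35 ± 0.18 (adjusted p = 0.456). Values for the erythroid aminolevulinate synthase genes were 0.35 ± 0.16 for alas2.L and 0.27 ± 0.12 for alas2.S, with adjusted p of 0.343 and 0.317. Of the 27 erythroid genes measured, 1 rose and 0 fell (2 and 0 adjusted over the list alone); this was the globin gene hbg2.L, whose log2 fold change was 2.23 ± 0.50 (adjusted p = 0.0335). Its call ended without control A, B, C or E, or without lead 630 A, C or E (adjusted p up to 0.102).

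In the list of endoplasmic reticulum (ER) stress and the integrated stress response 20 of 66 members rose and 0 fell (26 and 1 adjusted over the list alone). The chaperone genes hsp90b1.L and hspa5.L rose by 0.71 ± 0.07 (91.1 ± 3.12 to 149.6 ± 10.6 CPM, adjusted p = 2.52e-06) and by 0.56 ± 0.06 (59.9 ± 3.64 to 88.2 ± 2.83 CPM, adjusted p = 1.43e-05). Of 35 heat shock and cytosolic chaperone genes 4 rose and 0 fell (5 and 1 adjusted over the list alone). The 4 were both copies each of hspd1 and hspe1, the chaperonins of mitochondria, with 0.71 ± 0.08 for hspd1.S and 0.75 ± 0.10 for hspe1.S. The list call was lost with an estimated correlation (adjusted p = 0.0521).

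Genes of the aryl hydrocarbon and drug metabolism list rose in 5 of 33 cases and fell in 0 (11 and 3 adjusted over the list alone). The glucuronidation enzyme gene ugt1a1.L rose by 2.09 ± 0.16 (adjusted p = 2.05e-07) and aldh1a1.L, an aldehyde dehydrogenase of retinoic acid synthesis, by 1.35 ± 0.13 (adjusted p = 3.49e-06); the others were sult2b1.L, cyp3a5.L and abcg2.L. In the kidney list 5 of 32 rose and 0 fell (7 and 1 adjusted over the list alone). These encode transporters, slc22a6.S (2.44 ± 0.22), slc22a8.S, slc34a2.S and slc34a2.L, and the glutathione S-transferase gsta1.L (2.16 ± 0.14), also a member of the glutathione list. The kidney call was lost with an estimated correlation (adjusted p = 0.226).

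Fatty acid oxidation and PPAR target genes rose in 8 of 49 cases and fell in 0 (25 and 1 adjusted over the list alone), with acot2.S at 0.78 ± 0.13 and ech1.L at 0.32 ± 0.06, and the list had an adjusted p of 0.276 with an estimated correlation. In oxidative phosphorylation 4 of 96 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.506 with an estimated correlation), namely the cytochrome c genes cycs.L (0.72 ± 0.15) and cycs.S, with cyc1.L and sdhd.S. The call of cycs.S ended without control A or C, or without lead 630 A, C or E (adjusted p up to 0.0877). In 3 further lists that did not pass by camera few members rose and 0 fell. In glycolysis and gluconeogenesis 3 of 52 rose (5 higher and 4 lower adjusted over the list alone; adjusted p = 0.537): gck.L (0.71 ± 0.10), gpi.S (0.39 ± 0.07) and slc2a2.S. In hypoxia 1 of 50 rose (2 and 0 adjusted over the list alone; adjusted p = 0.504), igfbp1.S (0.92 ± 0.13). In cholesterol synthesis 1 of 42 rose (2 and 0 adjusted over the list alone; adjusted p = 0.13), the low density lipoprotein receptor gene ldlr.L (0.49 ± 0.11), a call that ended without control B or E, or without lead 630 A, B or E (adjusted p up to 0.0705).

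Fewer genes fell. The largest decreases among named genes with a mean of at least 1 CPM were in clca1.2.L, a calcium-activated chloride channel regulator (65.7 ± 52.4 to 1.81 ± 1.40 CPM, log2 fold change -5.25 ± 1.06, adjusted p = 0.0192), and in noxo1.S, an organizer of the epithelial NADPH oxidase (-3.07 ± 0.40, adjusted p = 0.000132). They were followed by the dual oxidase gene duox2.L (-2.46 ± 0.60, adjusted p = 0.0479), the aquaporin gene aqp10.L (-2.35 ± 0.34, adjusted p = 0.000567), tm4sf20.L (-1.88 ± 0.36) and the myostatin family gene mstn.2.S (-1.48 ± 0.32). At lead 630 noxo1.S stood at 0.514 ± 0.208 CPM, near the floor, and clca1.2.L at 0 CPM in lead 630 B. The size of these 2 falls is therefore uncertain. Left-out libraries ended the call of duox2.L in 9 of 10 runs, all but that without control A (adjusted p up to 0.127). They ended that of clca1.2.L without lead 630 C or E (up to 0.0695) and that of mstn.2.S without lead 630 C (0.0598).

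Tissue lists also held genes that fell. Of 59 cartilage and bone matrix genes 8 fell and 0 rose (22 and 0 adjusted over the list alone), and 3 of the 59 had a positive fold change. The cartilage collagen gene col2a1.L fell from 1028 ± 150.0 to 699 ± 61.4 CPM (-0.56 ± 0.12, adjusted p = 0.0145) and col9a3.S had a log2 fold change of -0.72 ± 0.16 (adjusted p = 0.0203), a call that ended without control A or D, or lead 630 B or E (up to 0.0635). With an estimated correlation of 0.398 between its genes the list's adjusted p was 0.234. Of 70 photoreceptor and visual cycle genes 4 fell and 0 rose (6 and 0 adjusted over the list alone), all of the visual cycle: rdh5.S (-0.90 ± 0.16), rdh5.L (-0.82 ± 0.15), rpe65.L and rgr.S. The list itself did not pass (adjusted p = 0.065), its test pointing down while its median was 0.001. In the thyroid hormone list 1 member rose and 3 fell of 33 (1 and 3 adjusted over the list alone; adjusted p = 0.265, with a median of 0.04 and a mean of -0.10). The iodide-recycling enzyme gene iyd.L rose by 1.22 ± 0.21 and dio3.L, whose product inactivates thyroid hormone, fell by 0.48 on the log2 scale (SE 0.10, adjusted p = 0.0113); duox2.L and ttr.L were the others that fell. Neither klf9.L (0.13 ± 0.34, adjusted p = 0.925) nor thrb.S (-0.07 ± 0.24, adjusted p = 0.946) passed. Of 66 keratinocyte genes 2 fell and 0 rose (2 and 0 adjusted over the list alone; adjusted p = 0.506 with an estimated correlation), krt12.2.S (-0.39 ± 0.08) and upk3a.L (-0.38 ± 0.09), the latter not without control A, B or D, or lead 630 B or E (adjusted p up to 0.0873).

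**Figure D1:**
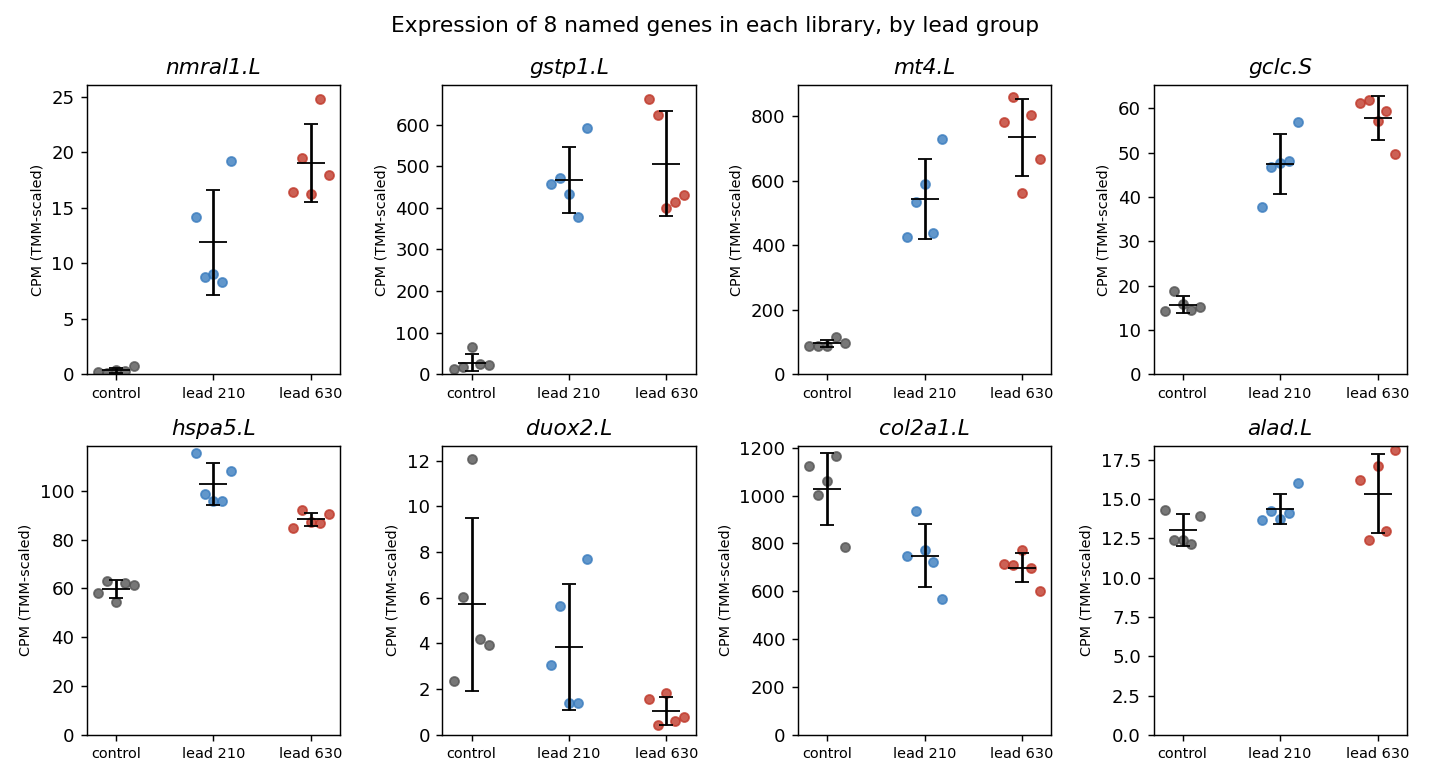
Expression of 8 named genes in CPM (vertical axes, each from 0) in the 5 libraries of each group (points), with group means and SD (bars). The exposed libraries of gstp1.L, mt4.L and gclc.S all lie above the controls, and the libraries of alad.L overlap between the groups, with means of 13.0, 14.4 and 15.4 CPM.

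In all, 617 genes differed between lead 630 and control by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 535 higher and 82 lower, and 178 of them at least 2-fold. The number of lower genes was 193 by DESeq2 and 154 by edgeR's exact test. It also depended on single libraries: it was 44 without control C, 45 without lead 630 C and 48 without lead 630 E. By camera with a preset correlation 19 of 37 lists passed, 10 upward and 9 downward, but 13 of 100 regroupings of these 10 libraries gave at least as many. With an estimated correlation 5 lists passed, all upward: glutathione and NRF2 targets (adjusted p = 2.02e-05), heme synthesis (0.0072), metal handling (0.00721), aryl hydrocarbon and drug metabolism (0.0261) and ER stress (0.0417). The other 14 had adjusted p of 0.0521 to 0.746 with an estimated correlation. They include intestine, cell proliferation, skeletal and heart muscle, glia, neurons, ribosomal proteins and epidermal goblet cells, besides those given above. With fry 10 lists passed, 9 upward and 1 downward, cartilage and bone matrix (adjusted p = 0.0415 by fry). The upward ones included heat shock (0.000785), kidney (0.0152) and fatty acid oxidation (0.0206).

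Lead 210 against control put the same question at the lower level, and the same 5 lists passed with an estimated correlation. Glutathione and NRF2 targets rose in 30 of 58 cases and fell in 0 (33 and 0 adjusted over the list alone; adjusted p = 5.94e-05 with an estimated correlation), with a median log2 fold change of 0.45. The gene gstp1.L reached 466 ± 78.4 CPM (4.07 ± 0.41, adjusted p = 6.05e-05), gclc.S 47.4 ± 6.86 CPM (1.60 ± 0.10) and me1.L 56.6 ± 3.28 CPM (1.05 ± 0.07). The gene nmral1.L rose by 5.03 ± 0.37 on the log2 scale, nmral1.S by 3.69 ± 0.36, slc34a2.S by 3.65 ± 0.66, and the carnitine and organic cation transporter gene slc22a4.S by 3.09 ± 0.19 (adjusted p = 1.37e-08).

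Metal handling genes rose in 8 of 38 cases and fell in 1 (14 and 4 adjusted over the list alone; adjusted p = 0.00875 with an estimated correlation). Expression of mt4.L stood at 543 ± 124 CPM (2.51 ± 0.15, adjusted p = 2.19e-08) and that of fth1.2.L at 1151 ± 213 CPM (2.04 ± 0.13). The member that fell was the zinc importer gene slc39a4.S (-1.20 ± 0.22, adjusted p = 0.00635). Heme synthesis rose in 5 of 23 cases (6 adjusted over the list alone) and fell in 0 by both counts, with abcb6.L (0.70 ± 0.06), abcb10.S, alas1.S, tmem14c.L and slc25a37.S. As at lead 630, alad.L (0.14 ± 0.10, adjusted p = 0.629) and alad.S (0.40 ± 0.18, adjusted p = 0.367) did not pass. In the ER stress list 21 of 66 rose and 0 fell (32 and 2 adjusted over the list alone), with hsp90b1.L at 178 ± 16.8 CPM (0.97 ± 0.07, adjusted p = 7.63e-08) and hspa5.L at 103 ± 8.65 CPM (0.78 ± 0.06). In the drug metabolism list 6 of 33 rose and 0 fell (11 and 0 adjusted over the list alone), among them ugt1a1.L (1.91 ± 0.16) and the sulfotransferase gene sult2b1.L (1.52 ± 0.16). The kidney list again had 5 of 32 higher and 0 lower (7 and 1 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), with slc22a6.S at 1.92 ± 0.23.

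Intestinal genes were higher in 4 of 39 cases and lower in 0 (11 and 0 adjusted over the list alone), and 35 of the 39 had a positive fold change; with an estimated correlation the list's adjusted p was 0.243. They were amn.L (0.96 ± 0.18), of the receptor for vitamin uptake, the brush border peptidase genes enpep.L (1.39 ± 0.27) and dpp4.L, and apob.L, whose call ended without control A, B, D or E (adjusted p up to 0.0713). Fatty acid oxidation genes rose in 7 of 49 cases and fell in 0 (19 and 0 adjusted over the list alone; adjusted p = 0.243 with an estimated correlation), with ehhadh.S at 0.54 ± 0.08. The glucose transporter gene slc2a2.S rose by 1.24 ± 0.20 and gck.L by 0.73 ± 0.10. Of 91 cell proliferation genes 3 fell and 0 rose (3 and 0 adjusted over the list alone), namely kif23.L (-0.79 ± 0.18), cdk1.L (-0.56 ± 0.13) and mcm5.S, and the list's adjusted p was 0.227 with an estimated correlation. The call of kif23.L ended without control A, B or E, or lead 210 D or E (up to 0.0813), and that of cdk1.L in 7 of 10 runs, all but those without control B, lead 210 B or lead 210 C (up to 0.0982). In the cartilage list 1 of 59 fell and 0 rose (2 and 0 adjusted over the list alone), col9a3.S at -0.65 ± 0.16 (adjusted p = 0.0434), a call that held in the runs without control E or lead 210 B and ended in the other 8 (up to 0.116). In the photoreceptor list 2 of 70 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.366 with an estimated correlation), prph2.L (-0.36 ± 0.08, not without control E or lead 210 A, adjusted p up to 0.0787) and rgr.S (-0.50 ± 0.12, a call that ended in 7 of 10 runs, all but those without control E, lead 210 A or lead 210 C, up to 0.106). The aquaporin gene aqp10.L fell by 2.23 on the log2 scale (SE 0.34, adjusted p = 0.00115) and dio3.L by 0.47 (SE 0.10, adjusted p = 0.0174; not without control D or lead 210 A, up to 0.0563).

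In all, 515 genes differed between lead 210 and control by edgeR's quasi-likelihood test, 476 higher and 39 lower, and 156 at least 2-fold. The exact test of edgeR called 856 (128 lower) and DESeq2 782 (117 lower). The number of lower genes was 17 without control A, 17 without control B, 19 without lead 210 A and 12 without lead 210 D. By camera with a preset correlation 20 of 37 lists passed, and 5 of 100 regroupings of the libraries gave at least as many. With an estimated correlation 5 lists passed, all upward, so that none of the 10 downward calls remained. With fry 12 lists passed, 10 upward and 2 downward. The downward lists were calcium handling (adjusted p = 0.0155 by fry) and cell proliferation (0.0309).

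**Figure D2:**
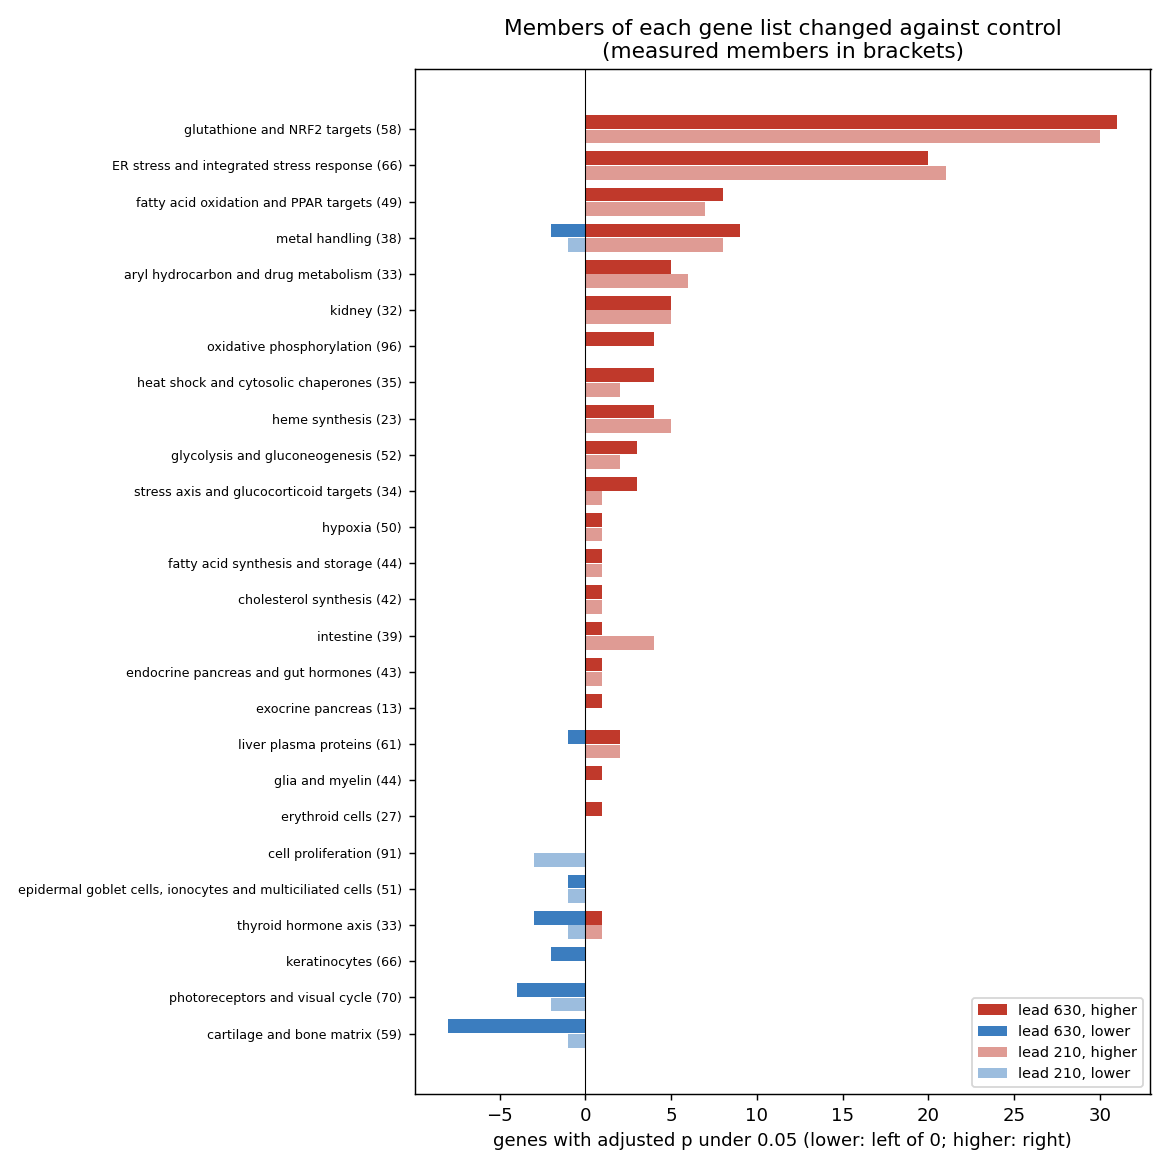
Members of each fixed gene list past an adjusted p of 0.05 against control (horizontal axis, number of genes, higher to the right of 0 and lower to the left), for lead 630 (full colour) and lead 210 (pale), with the measured members in brackets. Glutathione and NRF2 targets lead with 31 and 30 higher members, and the cartilage list has 8 and 1 lower.

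Exocrine pancreas genes behaved differently from the rest of the lists because of the library control B. In it the chymotrypsin gene ctrc.L stood at 610.9 CPM, against at most 21.7 CPM in any other library, and 7 of the list's 13 genes were at their highest of the 15 libraries there. The list's median log2 fold change was -2.64 at lead 630 and -3.00 at lead 210, while camera gave the opposite sign and no call (adjusted p = 0.313 and 0.335). Of the 13 genes 1 rose at lead 630 and 0 at lead 210 by the quasi-likelihood test, and 0 fell in either (3 higher and 3 lower, and 5 higher and 7 lower, adjusted over the list alone). The 1 was gp2.L, a call that ended in 7 of 10 runs, all but those without control D, control E or lead 630 D (adjusted p up to 0.11). Without control B, 531 genes differed at lead 630 and 418 at lead 210.

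The calls of both comparisons shared 381 higher and 18 lower genes, and no gene was called in opposite directions. Both comparisons use the same 5 controls. In 12 runs, simulated groups without any effect had 0 calls at lead 630 and at most 1 at lead 210. Their median of 0 shared calls was thus fixed in advance. It does not show how many shared calls the common controls bring among called genes. All simulations drew the genes independently of one another, so the ranges they give below may be too narrow. Independent lists of these sizes would share 9.41 higher and 0.118 lower genes. With the controls split into 2 and 3, one part for each comparison, the median over 20 splits was 196.5 shared calls in the same direction (174 to 239). Across genes, which are not independent replicates, the fold changes at the 2 levels had a correlation of 0.798, against a median of 0.5 in the simulations, and the covariance was 0.075 against 0.019. With split controls no control is shared: the median correlation was 0.379 (0.171 to 0.507), against 0.00536 in 12 simulations with split controls (-0.0349 to 0.0318), and the covariance 0.0435 (0.0222 to 0.0547) against 0.00032 (-0.0021 to 0.0019).

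**Figure D3:**
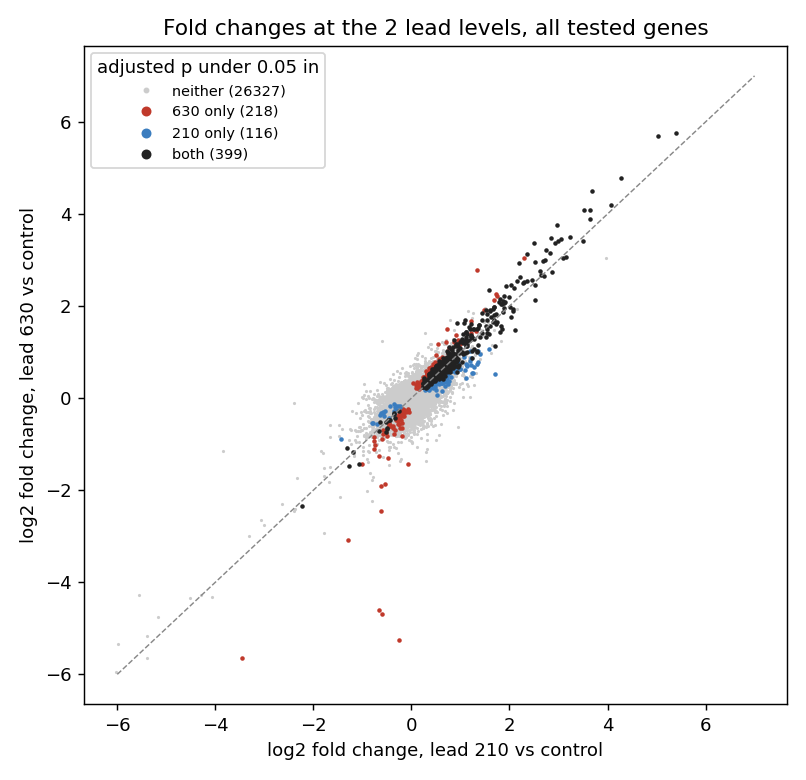
Log2 fold changes of all 27060 tested genes at lead 210 (horizontal) and lead 630 (vertical), each against the same 5 controls, with equality as a dashed line; colours mark genes past an adjusted p of 0.05 in neither, 1 or both comparisons. The 399 genes called in both lie close to the line.

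The direct comparison of lead 630 with lead 210 asked whether expression differs between the levels. By edgeR's quasi-likelihood test 0 genes passed (smallest adjusted p = 0.261, for the gene LOC100036818, which passed without lead 630 E at 0.012). Of the 27060 genes, 1260 had an unadjusted p under 0.05, fewer than the share of 0.05 that no difference would give. This number depended on single libraries, from 835 without lead 210 A to 2173 without lead 210 E. Among the 733 genes called at either level, 144 had an unadjusted p under 0.05 by the same test, more than a share of 0.05. Their calls rest on the same libraries, so this is no independent test. Of the 399 genes called at both levels, 269 had the larger change at lead 630. edgeR's exact test called 15, DESeq2 6 and limma-voom 0. The named genes with the smallest p, none past the threshold by the quasi-likelihood test (adjusted p = 0.932 each), were higd1a.S (0.61 ± 0.12), dcc.L (0.52 ± 0.13) and cnr1.L (0.42 ± 0.11) with positive values, and sdc4.S (-0.63 ± 0.13), hspa5.S (-0.36 ± 0.08) and elovl3.L (-0.82 ± 0.18) with negative ones. Of these, higd1a.S and sdc4.S passed by DESeq2 (adjusted p = 0.0242 and 0.03). Of the 733 genes called at either level, 687 (93.7%) had a 95% interval of the difference within 2-fold. These genes were chosen by being called, which favours small standard errors, so the share does not carry over to other genes. Most of them changed less than 2-fold against control, so the share does not show equal responses either. The intervals also rest on back-calculated SEs, which are unreliable for differences near 0. A gene called at only 1 level, 218 at lead 630 and 116 at lead 210, is not thereby shown to differ between them. Each of these had the same sign at the other level, but the shared controls favour that. In the simulations without any effect a median of 66.45% of all genes had the same sign in both comparisons.

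Of the lists, glutathione and NRF2 targets had a median difference of 0.13 between the levels, with 40 of 58 members positive, and ER stress one of -0.07, with 24 of 66 positive. Their members passed in 0 cases over all genes, and adjusted over the list alone in 0 cases for glutathione and in 4 for ER stress, all lower at lead 630. By camera with a preset correlation 12 lists passed, which 62 of 100 regroupings matched or exceeded, and with an estimated correlation 0 did (adjusted p = 0.592 for glutathione and 0.603 for ER stress).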

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

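The tests on regroupings were chosen before their results were seen. In 357 groups of 5 libraries, formed by the named genes, the mean of each gene list and the library totals, 18 held a library whose gap to the nearest other exceeded 0.71 of the group's range. Chance gives such a gap in about 5% of groups, or 17.9 of them, so the number as a whole is what chance gives. Among controls, gstp1.L stood at 64.2 CPM in replicate C (next 23.5), krt12.2.S at 71.4 CPM in D, slc2a2.S at 3.51 CPM in C, and me1.L and gjb1.L lowest in A at 24.6 and 9.32 CPM. At lead 210, replicate B was highest for akr1c2.L (211 CPM) and aqp10.L (4.1 CPM). Replicate E of lead 210 was highest for gsta1.L (74.6 CPM) and alad.L (16.1 CPM) and lowest for rdh5.S (3.71 CPM). At lead 630, pyy.L was highest in A at 8.88 CPM and slc39a4.S highest in C at 19.8 CPM.

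Of the list means, on the log2 CPM scale, lead 210 E was lowest for heat shock and cytosolic chaperones (4.23), lens crystallins (1.93, next 3.88) and heart muscle (3.86). Lead 210 C was highest for epidermal goblet cells, ionocytes and multiciliated cells (3.33), and lead 630 D lowest for the thyroid hormone axis (2.52). Replicate E of lead 210 thus held 6 of the 18. The total of lead 210 D, 22.32 M counts, lay above the other libraries of its group, the next being 14.63 M.

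Each comparison was set against 100 regroupings of its 10 libraries, the real one included. For genes at lead 630, 1 of 100 gave as many as the real 617 (highest other 16). For genes at lead 210, 1 of 100 gave as many as the real 515 (highest other 5). In each case this 1 is the real grouping, so the test could reach no lower share. That argues against a chance division of the libraries without excluding it. The other regroupings mix exposed and control libraries, which lowers their counts. The test cannot separate lead from a dish or clutch that the pools of a group may share. For lead 630 against lead 210 the real count was 0 (highest other 3), which any regrouping reaches, here 100 of 100, so this test says nothing about chance. For the number of lists past camera's preset correlation chance cannot be excluded. There 13 gave at least the real 19 at lead 630 (highest other 23) and 5 at least the real 20 at lead 210 (highest other 21). Between the levels 62 gave at least the real 12 (highest other 18). Regroupings that exchange 1 library keep most of a lead effect, and the others reaching 20 at lead 210 were of that kind. They are therefore no reference without an effect.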

How the results depend on the processing

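All alternatives here were planned before the data were examined, except the shared calls without control B, chosen after seeing the data. Counts within 1.5 times of the reported ones came from each filter, each normalization, limma-voom, summed homeologs and 2-group fits, and from each library left out: 439 to 697 genes at lead 630 (617 reported) and 355 to 488 at lead 210 (515). At lead 210 the exact test called 856 genes and DESeq2 782. Lower genes moved more: 154 and 193 at lead 630 (82 reported) and 128 and 117 at lead 210 (39). Between the levels the exact test called 15, DESeq2 6, and runs without a library 0 to 1, the 1 being LOC100036818 without lead 630 E (adjusted p = 0.012, against 0.261 with all libraries). Lists past the threshold numbered 5, 5 and 0 with an estimated correlation and 10, 12 and 0 with fry, against 19, 20 and 12; left-out libraries gave 15 to 22, 19 to 24 and 10 to 17. Shared calls were 399, with split controls a median of 196.5, where fewer controls per comparison lower the number of calls, and 338 without control B. Signs turned in 2 genes far from the threshold, with a library left out: klf9.L at lead 630 ran from -0.11 to 0.32 (3 runs below 0: -0.003, -0.07 and -0.11) and thrb.S from -0.21 to 0.03 (4 above 0: 0.026, 0.018, 0.031 and 0.018). For the exact test, DESeq2, fry, the estimated correlation and the turned signs the cause was not tested. Of 121 named values, 88 kept direction and side of the threshold under RLE factors, the replicate block, DESeq2 and each library left out. The replicate letters were not taken as pairs, since 8 of 15 same-letter pairs correlated above 0.1 (range -0.118 to 0.311) and 6 of 15 libraries correlated best with their own letter. Something shared by letter is not excluded: the median was 0.119, against -0.0165 for the 60 other pairs, and in each group A and B lay lower on the first principal component than D and E. With the replicate block 748, 691 and 0 genes passed (142, 88 and 0 lower, against 82, 39 and 0), and 11 of the named calls ended. They were, at lead 630, adh1-a (adjusted p = 0.0595), duox2.L (0.086), tm4sf20.L (0.0517), hbg2.L (0.053), gp2.L (0.071), upk3a.L (0.0533) and cycs.L (0.0647), and at lead 210 adh1-a (0.0809), apoa5.S (0.0577), rgr.S (0.0563) and cdk1.L (0.0504). Leaving out libraries was not run with the estimated correlation. Changes under 1.5-fold are less often found at this depth and n.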

Other observations

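More gene groups held called genes at both lead levels; their lists were drawn up after the values were seen, so the counts describe these libraries and are no independent evidence. Of 52 genes of sulfate and sulfur amino acid metabolism 15 were higher and 1 lower at lead 630, and 16 and 0 at lead 210; 4 of the higher genes at each level are members of the lists in the report. The gene papss2.S, of the enzyme that makes the sulfate donor PAPS, rose by 3.42 ± 0.13 and 2.99 ± 0.13 on the log2 scale, from 25.7 to 276 and 205 CPM. The sulfate transporter genes slc26a2.L (2.64 ± 0.20 and 2.70 ± 0.20) and slc13a1.L (1.88 ± 0.29 and 2.08 ± 0.29) rose too. So did cth.L of cysteine synthesis (1.16 ± 0.09 and 1.12 ± 0.09) and ethe1.S of sulfide oxidation (1.97 ± 0.15 and 2.02 ± 0.15). Of their other copies, papss2.L (1.17 ± 0.16 at lead 630) and slc13a1.S (1.815 ± 0.308) passed at both levels. The copies slc26a2.S (-0.06 ± 0.34 at lead 630), cth.S (-0.125 ± 0.37) and ethe1.L (0.80 ± 0.36) passed at neither. Of 39 iron genes 10 were higher and 0 lower at each level, and 6 of the 10 are members of those lists, so most of this count repeats the metal, heme and glutathione results. They include the ferritin gene fth1.1.S, from 2901 to 6319 CPM at lead 630, and the transferrin receptor gene tfrc.L (0.72 ± 0.11 and 0.55 ± 0.11). The ferritin degradation receptor gene ncoa4.L is another (0.64 ± 0.08 and 0.45 ± 0.08). The copy fth1.1.L passed at both levels (1.70 ± 0.12 at lead 630), while tfrc.S (0.089 ± 0.185) and ncoa4.S (0.106 ± 0.068) passed at neither. Of 27 brush border genes of enterocytes 4 were higher at lead 630 and 10 at lead 210 (0 and 2 of them in those lists), with 0 lower. Among those higher were lct.2.L (1.42 ± 0.15 and 1.54 ± 0.15) and the cholesterol transporter gene npc1l1.S (1.56 ± 0.18 and 1.83 ± 0.18). The copy npc1l1.L passed at neither level (-0.455 ± 0.374 at lead 630).

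In the paragraphs that follow, the tests on mislabelling, on intestinal cells, on fold changes without a control, on the dose ratio and on power were chosen after the result was seen. Exocrine pancreas enzymes were far higher in control B: ctrc.L stood at 610.9 CPM, cpa1.L at 536.9 and ctrb1.L at 324 CPM, and the list's median excess over the other controls was 5.40 on the log2 scale. Of the 6 most raised genes at lead 630, 0 reached the lowest lead library there. Those 6 were picked with control B counted as a control, which favours this result. The glutathione and NRF2 list was fixed before the data, and its mean log2 CPM in control B was 4.5. The other controls ran from 4.393 to 4.603, and the lowest lead library, lead 210 D, stood at 5.178. These values argue against a lead library under a control label. An embryo further along in digestive development could be in the pool, but 0 of 3 digestive lists stood 0.3 or more above the other controls (liver 0.28, where the other controls ran from -0.39 to 0.56, intestine -0.32 and gut hormones -0.03). The liver value lay inside the range of the other controls, and the intestine value under their lowest (-0.259). These lists thus give no sign of such an embryo, but they do not exclude one. RNA with mature pancreas transcripts carried into the library cannot be told apart from acinar cells of the pool itself, because both bring the same transcripts. In control C the 5 leading enzymes stood at 0.955% to 1.08% of their level in control B, in lead 210 C at 1.40% to 2.62%, in lead 630 B at 1.45% to 4.69%, and in the other libraries at or under 0.473%.

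In a set of mucosal oxidase and mucus genes drawn up after the values were seen, and given no set test, 5 of 11 fell and 0 rose at lead 630 by the quasi-likelihood test, against 0 and 0 at lead 210. The 5 were clca1.2.L, noxo1.S, duox2.L, clca1.1.L and tm4sf20.L. The other 6 did not pass: log2 fold changes were positive for muc2l.L (0.38), agr2.L (0.50), agr2.S (0.24) and spdef.S (0.13) and negative for tm4sf20.S (-0.51) and noxa1.L (-0.34). The median of the 11 was -0.51. The 5 genes that fell at lead 630 also had negative values at lead 210, none past the threshold by the quasi-likelihood test. That of noxo1.S was -1.30 ± 0.35 (adjusted p = 0.0711), and the others ran from -0.06 (clca1.1.L) to -0.62 (duox2.L). The intestine list gave no sign of fewer intestinal cells against control, as its median log2 fold change was 0.24 at lead 630. It cannot decide this, because the list rose at lead 210 too (median 0.325) and higher expression per cell would hide a loss. Against lead 210 its median at lead 630 was -0.123, with 12 of 39 members positive. A single control library that makes up the fold changes is argued against. With any 1 control left out each of the 5 genes kept at least 73.7% of its log2 fold change. The calls of clca1.2.L, noxo1.S and tm4sf20.L passed in each of these runs. That of duox2.L (-2.46 ± 0.60) ended without control B, C, D or E (-1.96 to -2.57, adjusted p up to 0.111) and that of clca1.1.L (-1.44 ± 0.33) without B, C or E (-1.06 to -1.51, up to 0.0738). So up to 2 of the 5 calls were decided by a single control. A response to the higher lead level remains a hypothesis, as the difference between the levels passed for 0 of the 5 genes by the quasi-likelihood test, for 1 by DESeq2 and for 4 by the exact test. Too little power to call a 2-fold difference stays open for these genes: 0 of the 5 had a 95% interval within 2-fold, and all 5 lay below 0, such as -7.29 to -2.70 for clca1.2.L (unadjusted p = 0.000458) and -3.17 to -0.52 for duox2.L (0.01).

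The rises at lead 630 were little larger than at lead 210, although the nominal level was 3 times as high. For the genes higher at both levels and called at 1 or both, by coincidence also 630 in number, the median ratio of the rise over control (fold minus 1) was 1.16, with an interquartile range of 0.861 to 1.39. That argues against expression rising in proportion to the nominal level. For 93.7% of the 733 genes called at either level the 95% interval of the difference lay within 2-fold. The median half-width of these intervals was 0.24 on the log2 scale. As far as the back-calculated SEs hold, that argues against too little power for 2-fold differences in those genes. It does not show equal responses. Only 178 of 617 called genes at lead 630 and 156 of 515 at lead 210 changed at least 2-fold against control. For smaller changes, even no response at 1 level could leave the difference within 2-fold. The rest of the 733 genes, the 5 mucosal genes among them, stay open. A response near its ceiling at the lower level may account for the similar rises, as may a difference in lead taken up that is smaller than that in the nominal levels. Neither was tested, and lead in the embryos is not analysed here.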
